A study of Caenorhabditis elegans with 6 samples.

How the data were processed

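RNA from whole L4 worms was sequenced in 3 mutant and 3 control samples. Per the labels' protocols, worms were synchronized at hatching, grown at 25 °C for 96 h (mutant) or 48 h (control), and 500 worms per sample were picked by distal tip cell migration, seen with a lag-2::GFP reporter. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a stranded total RNA kit that removes ribosomal RNA with probes designed for human, mouse and rat. Reads were 150 bp paired-end, per the labels. Ribosomal RNA genes held 14.2% of the summed mean normalized counts against 82.8% for protein-coding genes.

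The submitters' processing notes name cutadapt 2.7, HISAT2 2.1.0, Subread, featureCounts 1.6.4, R 3.5.1 and DESeq2 1.22.1, without saying in which order or with which settings. The genome build, the gene annotation, the strand setting and the handling of reads that match several genes are not given in the sources used here. The deposited file holds 1 comparison of the mutant with the control strain for 46932 genes. Per the file headers, the deposited mean is a signal averaged over all samples, namely counts divided by the size factors of DESeq2. Per the file headers, the authors also gave a log2 fold change of mutant over control with its standard error on the log2 scale, a test score (the Wald statistic), a p-value and an adjusted p-value. No values per sample were used here, so no total per sample, replicate spread or confidence interval of a level could be given, and the depth of each sample is unknown. The mean normalized counts summed to 12452607. The order of the strains was taken from the file's own name and agreed in direction with the fall of mir-52 in the mutant.

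The deposited values were tested before use. A mean of 0 was listed for 20463 genes, 26467 genes had a p-value, 18592 had an adjusted p, and 2 had a fold change without a p-value. The deposited p-values matched the 2-sided normal p of the score within 2.8e-15, and the adjusted p matched a Benjamini-Hochberg adjustment over the 18592 genes within 1.5e-15. Genes with a mean under 1.49 had no adjusted p, so rare transcripts were not tested. The standard error of the log2 fold change never passed 0.923, even among the 6855 genes with a mean under 1, whose log2 fold changes stayed within 1.54. The ratio of fold change to standard error, divided by the score, ran from 0.978 to 1.16 between its percentiles 1 and 99. The deposited fold changes therefore appear to have been drawn toward 0, most for genes with few reads, while p-values came from the score. Folds printed here are powers of 2 of these values.

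Gene names were matched by identifier. A table of gene names gave 42783 of them, and 4083 came from the RefSeq gene at exactly the same position of the same assembly, either because the table had no name or because it gave one name to several genes, as for many histones. Another 38 names came from the deposited symbols, and 28 genes kept their identifiers. Positions and gene types came from the Ensembl release 115 annotation of WBcel235, in which 13 of the identifiers were not found, and the authors' build may differ. Among protein-coding genes with no exon base shared with another gene on the same strand, 6.86% of 18350 were listed at 0, against 77.1% of 179 genes sharing at least 50% of their exon bases. Reads shared between overlapping genes thus seem often to have been left out. How reads shared between near-identical copies were handled was not tested. The germline regulator gene gld-1 was listed at 0 and the ubiquitin-conjugating enzyme gene let-70 had a mean of 0.316 in the authors' deposited table, although many cells use these genes, so a 0 is described only as listed at 0.

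Before the data were examined, a count test of the 6 samples had been planned, with the authors' own calls as the fallback if only their comparison was found. The fallback applied: genes were called changed at the authors' adjusted p under 0.05, and no test per gene was run here. Also fixed before the data were examined were 30 gene lists covering the mutated family, developmental timing, germline, cuticle, stress and markers of tissues, sexes and stages. Lists and gene families (name prefixes with at least 10 tested genes) were tested with cameraPR of limma 3.58.1 in R 4.3.3, 2-sided, on the authors' score, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 29 lists or the 158 families. The mir-51 family list had too few tested members for this test. Counts of members use the authors' adjusted p, and counts adjusted over the list alone apply Benjamini-Hochberg adjustment to the authors' p-values of the list's members. One member, daf-21, found no match by name. Tested on simulated data over the 18592 genes, lists shifted by 1 SD of the score were called in 86.2% of 160 draws and by 2 SD in 100%, and 4.07% of p-values fell under 0.05 in 100 permuted draws. These draws shuffled the scores over genes, which removes correlation between list members. They therefore do not show how often lists of correlated genes would be called falsely.

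The genes named were fixed by rule before the data were examined: the mir-51 family members; the 8 called genes with the largest rise and the 8 with the largest fall at a mean of at least 50; up to 3 called members per list with the largest change, or the member with the smallest p; the genes lin-14, lin-28, lin-41, hbl-1, lin-29, daf-12, col-19, lag-2 and cdh-3; and 2 members of each of the 10 families with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen. This also holds for gld-1, let-70 and skr-3. Genes with sites for the mir-51 family or for other microRNA families in their 3' untranslated regions were not analysed here, because no genome sequence was used. Alternatives tried were other thresholds, other filters on the mean, other preset correlations, other statistics and other backgrounds. Other tools were Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and bedtools 2.31.1 for overlaps.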

Results

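RNA was measured in whole Caenorhabditis elegans worms at the L4 stage, the last larval stage before adulthood. A strain carrying mutations in mir-52 and in the mir-54, mir-55 and mir-56 genes was compared with a control strain. These genes belong to the mir-51 family, small regulatory RNAs that share a seed sequence, which also includes mir-51 and mir-53. The comparison addressed how transcript levels differed in L4 worms when these family members were mutated. Each group had 3 samples of 500 worms, grown at 25 °C and picked by how far the distal tip cells, which lead the growing gonad arms, had migrated. Mutant worms had grown for 96 h and control worms for 48 h, so growth time separated the samples exactly as genotype did. Values came from the authors' deposited table, which gives 1 mean, 1 log2 fold change and 1 test per gene over the 6 samples. The depth of each sample is therefore unknown here, and the mean normalized counts summed to 12452607 over all genes. The labels do not say that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

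Relative to the other transcripts measured, RNA of oocyte genes, yolk protein genes and intracellular pathogen response genes was higher in mutant than in control L4 worms. RNA of molting genes, furrow collagens, ribosomal proteins and mitochondrially encoded genes was lower. Counts had been divided by size factors, so rises and falls here are relative, and amounts of RNA per worm are unknown. Of 18592 genes with an adjusted p in the authors' deposited table, 5917 (31.8%) changed at an adjusted p under 0.05, of which 3081 were higher and 2836 lower in the mutant. Large rises outnumbered large falls: a log2 fold change of at least 5 was reached by 207 genes that rose and by 11 that fell. The median over all tested genes was 0.02 on the log2 scale. The 8 rises of largest size among called genes with a mean normalized count of at least 50 belonged in the authors' deposited table to the cuticle collagen genes col-119 (log2 fold change 10.64, SE 0.52) and col-8 (9.69, SE 0.44), the gene ule-5 (10.14, SE 0.60) and 5 genes known by sequence names. Those were, in the authors' deposited table, ZK813.1 (10.27, SE 0.64), Y62H9A.5 (9.95, SE 0.58), W02D9.7 (9.83, SE 0.65), Y62H9A.4 (9.54, SE 0.64) and F55B11.3 (9.50, SE 0.61). The 8 falls of largest size among called genes with a mean normalized count of at least 50 in the authors' deposited table were dod-24 (-8.65, SE 0.47), irg-4 (-7.87, SE 0.54), fat-7 (-7.70, SE 0.45), irg-5 (-7.48, SE 0.44), sysm-1 (-5.95, SE 0.61), F55G11.4 (-5.74, SE 0.43), F55G11.8 (-5.51, SE 0.39) and Y48E1B.8 (-5.40, SE 0.60). Of these, irg-4, irg-5, dod-24 and sysm-1 are known as pathogen-inducible or immune-linked genes, and fat-7 encodes a fatty acid desaturase.

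**Figure D1:**
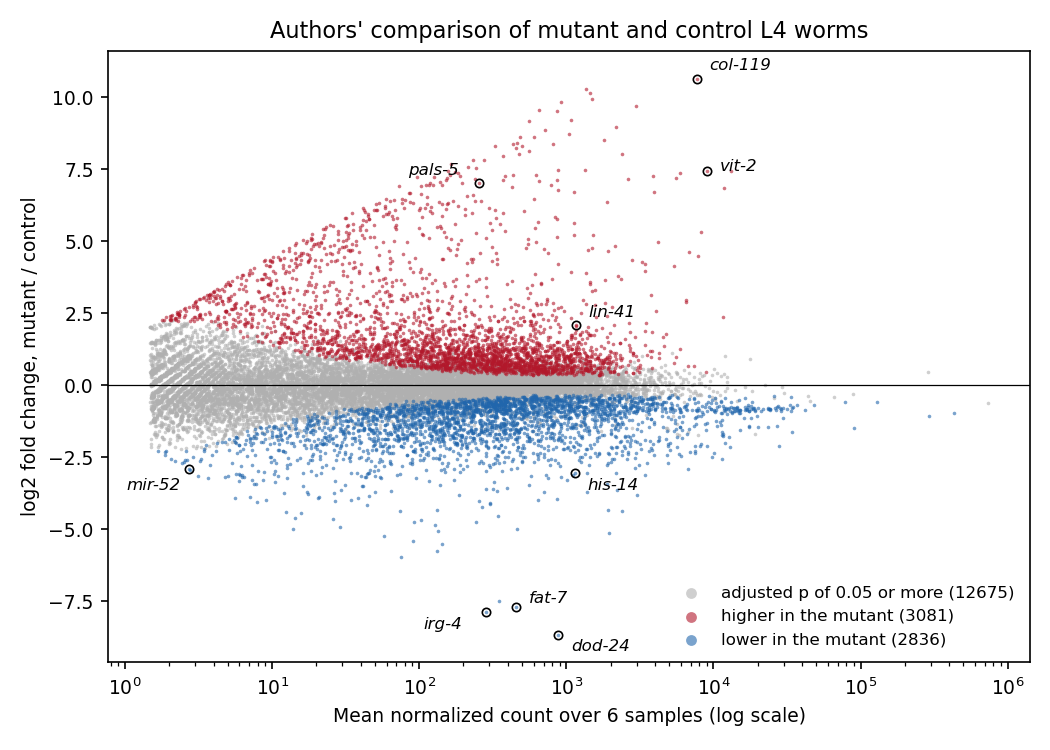
Each point is 1 of the 18592 tested genes of the authors' deposited table, with the mean normalized count over the 6 samples on a log horizontal axis and the log2 fold change of mutant over control on the vertical axis. The 3081 red points rose, the 2836 blue points fell, grey points did not pass an adjusted p of 0.05, and col-119 at 10.64 and dod-24 at -8.65 mark the top and bottom.

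The mutated genes themselves were measured near the detection floor. In the WBcel235 annotation, mir-52 lies on chromosome IV from 14034008 to 14034107 on the plus strand, over an exon of the noncoding gene WBGene00199919 on the opposite strand, which is listed at 0. Its RNA fell in the mutant, with a log2 fold change of -2.92 (SE 0.91, adjusted p = 0.00652) at a mean normalized count of 2.74 in the authors' deposited table. The other mutated genes lie together on the minus strand of the X chromosome, inside an intron of the protein-coding gene F09A5.3 on the plus strand: mir-54 from 13144996 to 13145094, mir-55 from 13144827 to 13144924 and mir-56 from 13144691 to 13144787. The authors' deposited table gave them no adjusted p, at log2 fold changes of -0.38 (SE 0.69) for mir-54, -1.90 (SE 0.92) for mir-55 and -2.03 (SE 0.92) for mir-56 and means of 0.377, 1.29 and 1.46. The overlapping gene F09A5.3, on the opposite strand, stood at 0.45 (SE 0.62, adjusted p = 0.648) in the authors' deposited table. The family members left intact in the strain's name lie on the minus strand of chromosome IV, mir-51 from 11026013 to 11026112 and mir-53 from 11027593 to 11027691. By the authors' deposited table mir-51 had a log2 fold change of -1.69 (SE 0.75, adjusted p = 0.0769, mean 4.08) and mir-53 had -0.27 (SE 0.78, mean 0.495, no adjusted p). Of the family list, 2 members had an adjusted p, of which 1 was called lower over all genes and 2 adjusted over the list alone.

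Genes of the female germline rose together. All 22 tested oocyte genes rose, over all genes and adjusted over the list alone, with a median log2 fold change of 2.47 (cameraPR adjusted p = 5.7e-40). Among them were perm-2 (5.23, SE 0.35) and perm-4 (4.61, SE 0.43), which encode eggshell components, and puf-5 (3.78, SE 0.28), which encodes an RNA-binding protein of oocytes, in the authors' deposited table. Of 5 tested vitellogenins, the yolk proteins made in the intestine of adult hermaphrodites, 4 rose over all genes and 5 adjusted over the list alone (median 5.64, cameraPR adjusted p = 2.79e-07). By the authors' deposited table the rises were 7.42 (SE 0.63) for vit-2, 6.83 (SE 0.59) for vit-6 and 5.64 (SE 0.87) for vit-5, with vit-1 at 1.41 (SE 0.62, adjusted p = 0.066) and vit-4 listed at 0. Naming vit-1 and vit-4 was decided after their values were seen. Sperm genes rose too: 24 of 33 tested genes of the major sperm protein list, 3 of them annotated as pseudogenes, rose and 1 fell, with the same counts adjusted over the list alone (quartiles 0.85 and 1.47, cameraPR adjusted p = 9.71e-06). The authors' deposited table gave msp-55 a log2 fold change of 2.60 (SE 0.37), msp-51 1.91 (SE 0.32) and msp-63 1.81 (SE 0.40). These genes are near-identical copies, so reads could be split between them and each single value is uncertain. Of 24 other spermatogenesis genes 11 rose and 0 fell, also adjusted over the list alone (median 0.63, cameraPR adjusted p = 0.00571), and the call ended at a preset correlation of 0.1 (adjusted p = 0.134). Examples in the authors' deposited table were spe-12 (1.89, SE 0.30), ssp-19 (1.86, SE 0.55) and ssp-10 (1.58, SE 0.39).

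Germline and meiosis genes had the lowest median of the germline lists. Of 25 tested members 8 rose and 0 fell, also adjusted over the list alone, with a median of 0.33 (cameraPR adjusted p = 0.0318, and adjusted p = 0.129 at a preset correlation of 0.05). The members with the largest rise in the authors' deposited table were glh-2 (1.16, SE 0.30), glp-1 (0.92, SE 0.25), the Notch receptor of germline stem cells, and zim-2 (0.86, SE 0.24). Cell cycle and DNA replication genes rose, with 18 of 25 higher and 1 lower over all genes, and 20 and 1 adjusted over the list alone (median 0.80, cameraPR adjusted p = 2e-06, and adjusted p = 0.0756 with the log2 fold change as the statistic). In the authors' deposited table the mitotic cyclins cyb-3 (1.91, SE 0.24) and cyb-1 (1.47, SE 0.19) were among the risers, and the member that fell was the G1 cyclin gene cyd-1 (-1.54, SE 0.43). Histone genes went the other way: of 59 tested, 25 fell and 2 rose over all genes, and 27 and 7 adjusted over the list alone (median -0.69, cameraPR adjusted p = 3.21e-06). The falls of largest size in the authors' deposited table were his-14 (-3.06, SE 0.19), his-19 (-2.99, SE 0.69) and his-9 (-2.47, SE 0.24), which have near-identical copies.

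Molting genes and furrow collagens fell, while adult-type cuticle genes went both ways. Of 22 tested molting genes 16 fell and 0 rose, and 17 fell adjusted over the list alone (median -1.74, cameraPR adjusted p = 1.6e-05). The hedgehog-related genes wrt-2 (-2.66, SE 0.58), wrt-10 (-2.65, SE 0.61) and wrt-1 (-2.57, SE 0.58) fell most in the authors' deposited table. Of 16 furrow and body-shape collagens, which pattern the ridged cuticle, 15 fell and 0 rose, also adjusted over the list alone (median -2.28, cameraPR adjusted p = 1.05e-05). They included lon-3 (-2.88, SE 0.65), dpy-17 (-2.59, SE 0.47) and sqt-3 (-2.57, SE 0.62) in the authors' deposited table. The 10 adult-type cuticle genes did not move as a set, with 3 higher and 3 lower over all genes, and 3 and 5 adjusted over the list alone. Their median was -1.56, while the test pointed to higher values (cameraPR adjusted p = 0.979), so median and test differed in sign. The adult collagen gene col-19 rose by 7.26 (SE 0.63), or 154-fold, in the authors' deposited table, with col-62 at 3.93 (SE 0.61) and col-7 at 2.91 (SE 0.91). The members that fell in the authors' deposited table were bli-1 (-2.89, SE 0.63) and bli-2 (-2.71, SE 0.63), collagens of the struts of the adult cuticle, and col-38 (-1.81, SE 0.67). Naming bli-1, bli-2 and col-38 was decided after their values were seen.

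**Figure D2:**
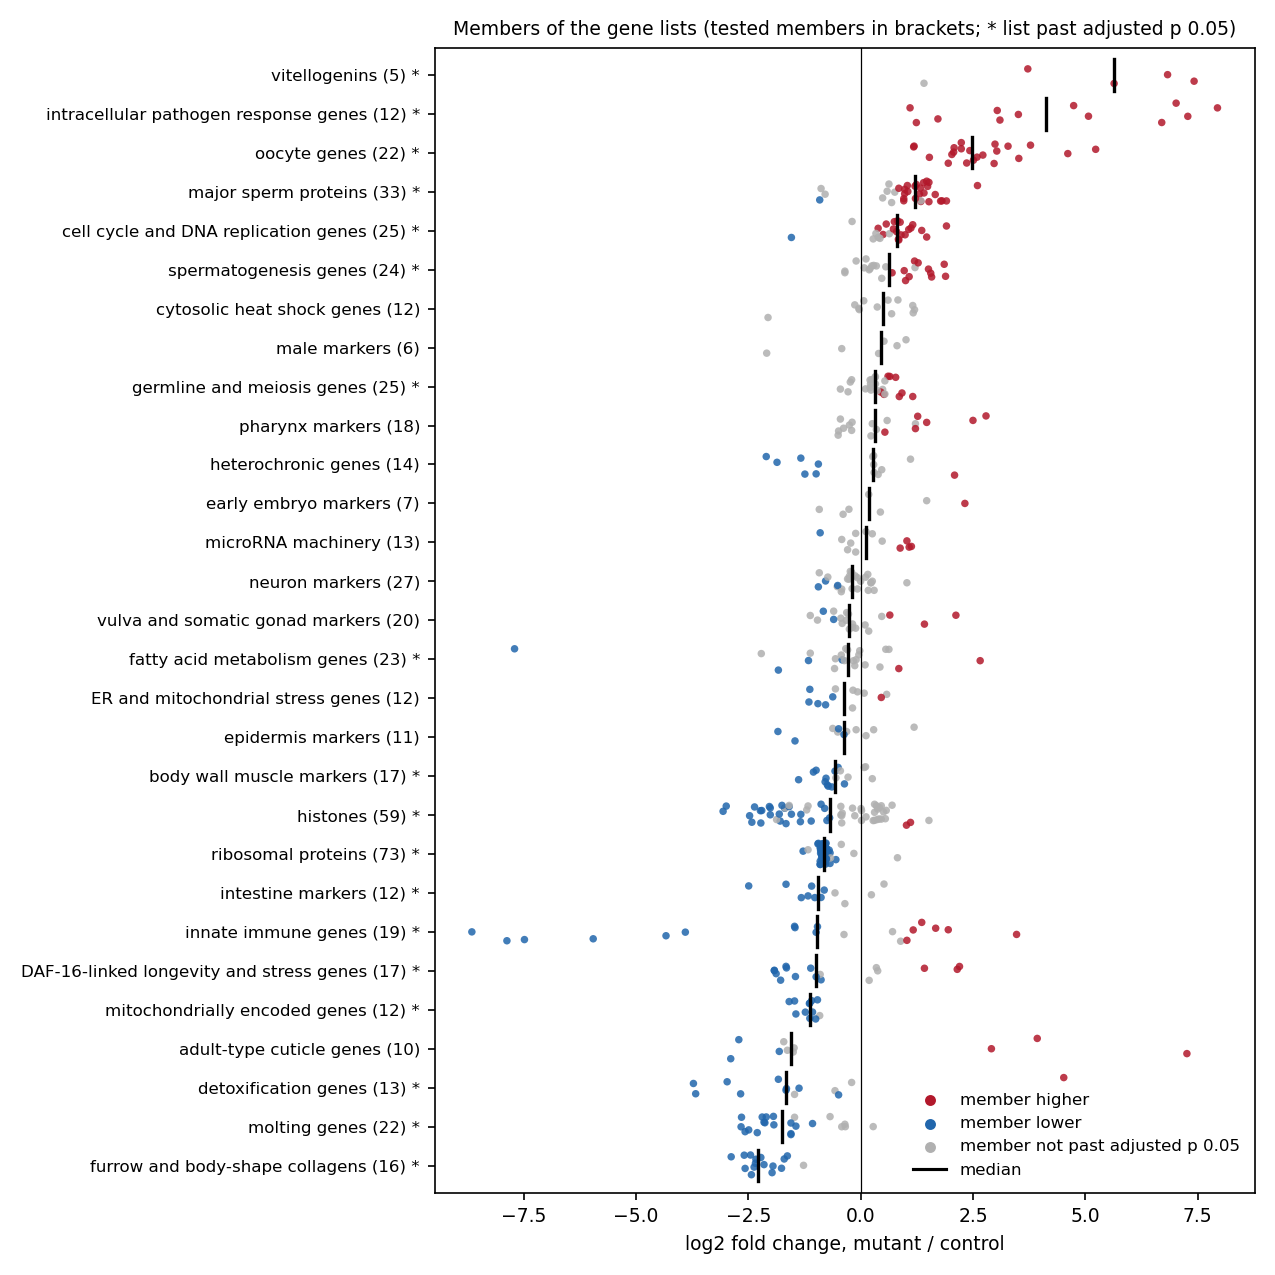
Each point is a tested member of 1 of the 29 gene lists with a test, placed by its log2 fold change of mutant over control in the authors' deposited table, with the number of tested members in brackets and black bars at the list medians. Vitellogenins (median 5.64), intracellular pathogen response genes (4.13) and oocyte genes (2.47) stand at the top, furrow and body-shape collagens (-2.28) at the bottom, and an asterisk marks a list past a cameraPR adjusted p of 0.05.

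Developmental timing (heterochronic) genes, which set the order of larval stages, went both ways. Of 14 tested members 1 rose and 6 fell over all genes, and 3 rose and 6 fell adjusted over the list alone. The list as a whole did not pass (median 0.28, test direction lower, cameraPR adjusted p = 0.355), with median and test of opposite sign. In the authors' deposited table lin-41, an RNA-binding protein gene repressed by the let-7 microRNA, rose by 2.09 (SE 0.43, adjusted p = 1.28e-05), or 4.26-fold. The period-like gene lin-42 (-2.10, SE 0.45) and the transcription factor gene blmp-1 (-1.86, SE 0.33) fell most in the authors' deposited table. Both hbl-1 (-0.94, SE 0.27, adjusted p = 0.00285) and lin-29 (-0.99, SE 0.22, adjusted p = 7.08e-05) were lower in the authors' deposited table as well. By the authors' deposited table, lin-14 stood at 0.29 (SE 0.26, adjusted p = 0.445), daf-12 at 0.29 (SE 0.31, adjusted p = 0.526) and lin-28 at 0.47 (SE 0.20, adjusted p = 0.059). The distal tip cell ligand gene lag-2 stood at -0.11 (SE 0.73, adjusted p = 0.932) with a mean of 5.7, and the cadherin gene cdh-3 at -0.96 (SE 0.55, adjusted p = 0.18), in the authors' deposited table. MicroRNA machinery did not move as a list, with 4 of 13 members higher and 1 lower, also adjusted over the list alone (median 0.12, cameraPR adjusted p = 0.612). Its members with the largest rise in the authors' deposited table were nhl-2 (1.13, SE 0.45, adjusted p = 0.04), the Argonaute gene alg-5 (1.08, SE 0.20) and the Drosha gene drsh-1 (1.03, SE 0.43, adjusted p just under 0.05).

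Stress and immune lists moved both ways. All 12 intracellular pathogen response genes, a set induced by microsporidia and virus infection, rose, also adjusted over the list alone (median 4.13, cameraPR adjusted p = 2.76e-14). In the authors' deposited table the rises were 7.94 (SE 0.70) for F26F2.4, 7.28 (SE 0.72) for F26F2.3 and 7.02 (SE 0.68) for pals-5. The control levels of these genes, as implied by the mean and the fold change plus 2 SE, lay under 10. The sizes of these rises are therefore uncertain. Innate immune genes, with roles against bacteria or fungi, fell as a list, with 10 of 19 lower and 6 higher over all genes, and 10 and 7 adjusted over the list alone (median -0.96, cameraPR adjusted p = 2.45e-06). The list call ended when ranks replaced the statistic (adjusted p = 0.185). Its named members, dod-24, irg-4 and irg-5, stood at -8.65, -7.87 and -7.48 in the authors' deposited table. Detoxification genes fell, with 9 of 13 lower and 1 higher, also adjusted over the list alone (median -1.65, cameraPR adjusted p = 0.000412). The cytochrome P450 gene cyp-35A3 (-3.72, SE 0.66) and the glutathione transferase gene gst-10 (-3.67, SE 0.42) fell in the authors' deposited table, while gst-30 rose (4.52, SE 0.75). Genes linked to the longevity factor DAF-16 fell as a list, with 10 of 17 lower and 3 higher over all genes, and 11 and 3 adjusted over the list alone (median -0.99, cameraPR adjusted p = 0.0234, and adjusted p = 0.0867 at a preset correlation of 0.05). In the authors' deposited table hsp-12.3 fell (-1.92, SE 0.33), and hil-1 (2.20, SE 0.42) and sip-1 (2.15, SE 0.36) rose. No cytosolic heat shock gene was called among 12, over all genes or adjusted over the list alone (median 0.49, cameraPR adjusted p = 0.612), and hsp-16.49, the member with the smallest p in the authors' deposited table, stood at -2.06 (SE 0.87, p = 0.017, adjusted p = 0.0528). For ER and mitochondrial stress genes, 5 of 12 were lower and 1 higher, also adjusted over the list alone, and the list did not pass (median -0.37, cameraPR adjusted p = 0.0659). Examples in the authors' deposited table were dnj-27 (-1.15, SE 0.33), the chaperone gene hsp-3 (-1.13, SE 0.15) and ckb-2 (-0.95, SE 0.32).

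**Figure D3:**
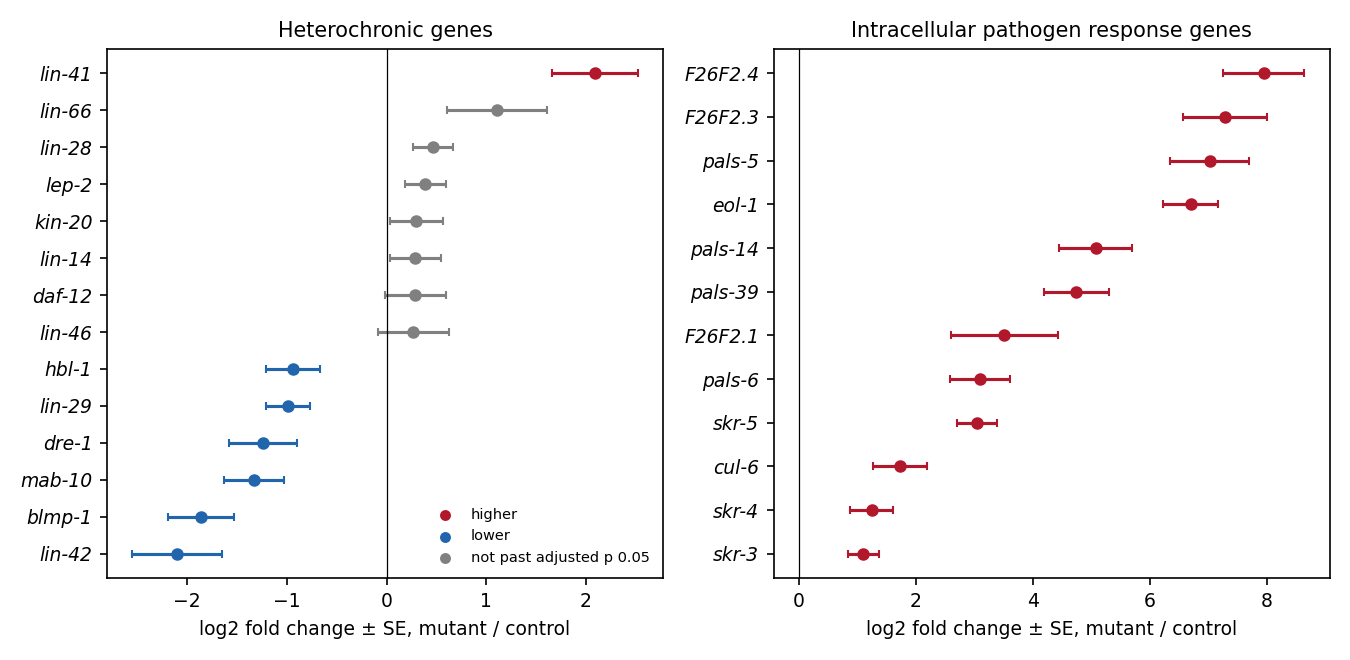
Points are log2 fold changes of mutant over control with standard errors from the authors' deposited table, for 14 heterochronic genes on the left and 12 intracellular pathogen response genes on the right. On the left lin-41 stands alone among red, raised genes at 2.09 and lin-42 lies lowest at -2.10, and on the right every gene is raised, from skr-3 at 1.10 to F26F2.4 at 7.94.

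Ribosomal protein genes and mitochondrially encoded genes fell. Of 73 tested ribosomal protein genes 68 fell and 0 rose over all genes, and 69 fell and 1 rose adjusted over the list alone (median -0.82, cameraPR adjusted p = 3.59e-19). Those with the largest fall in the authors' deposited table were rpl-11.2 (-1.28, SE 0.22), rpl-26 (-0.95, SE 0.19) and rpl-30 (-0.94, SE 0.19). Of 12 mitochondrially encoded protein genes 11 fell and 0 rose, also adjusted over the list alone (median -1.13, cameraPR adjusted p = 5.4e-07). They included ND3 (-1.59, SE 0.28) and the cytochrome oxidase subunits COX1 (-1.47, SE 0.19) and COX3 (-1.44, SE 0.18) in the authors' deposited table. Of 23 fatty acid metabolism genes 4 were lower, 2 higher and 17 not called, with 4 and 2 adjusted over the list alone, and the list passed toward lower values (median -0.29, cameraPR adjusted p = 0.0234). Its call ended at a preset correlation of 0.05 (adjusted p = 0.101) and with ranks (adjusted p = 0.0687). Beside fat-7, which fell by 7.70, the lipase genes lipl-4 (-1.83, SE 0.27) and lipl-1 (2.66, SE 0.46) were called in opposite directions in the authors' deposited table.

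Markers of somatic tissues shifted beside these groups. Intestine markers fell, with 8 of 12 lower and 0 higher, also adjusted over the list alone (median -0.95, cameraPR adjusted p = 0.000139). They included in the authors' deposited table the esterase gene ges-1 (-2.49, SE 0.21), pho-1 (-1.66, SE 0.32) and the intestinal actin gene act-5 (-1.32, SE 0.25). Body wall muscle markers fell, with 11 of 17 lower and 0 higher, also adjusted over the list alone (median -0.57, cameraPR adjusted p = 3.22e-05, and adjusted p = 0.0841 with the log2 fold change as the statistic). Among them were tni-1 (-1.38, SE 0.16), mlc-1 (-1.05, SE 0.15) and tnt-2 (-0.99, SE 0.21) in the authors' deposited table. Lists of other tissues, sexes and stages did not pass. Neuron markers had 3 of 27 lower and 0 higher (median -0.20, cameraPR adjusted p = 0.229), with the touch neuron tubulin genes mec-7 (-0.94, SE 0.21) and mec-12 (-0.78, SE 0.20) and with unc-119 (-0.51, SE 0.17) called in the authors' deposited table. Epidermis markers had 4 of 11 lower and 0 higher (median -0.37, cameraPR adjusted p = 0.182), among them nhr-73 (-1.84, SE 0.72), grh-1 (-1.46, SE 0.31) and dlg-1 (-0.49, SE 0.15) in the authors' deposited table. Pharynx markers had 6 of 18 higher and 0 lower (median 0.31, cameraPR adjusted p = 0.236), among them phat-5 (2.79, SE 0.57), abu-8 (2.50, SE 0.78) and myo-5 (1.47, SE 0.49) in the authors' deposited table. Vulva and somatic gonad markers had 3 of 20 higher and 2 lower (median -0.26, cameraPR adjusted p = 0.612), with hlh-12 (2.12, SE 0.72), inx-8 (1.42, SE 0.28) and mig-17 (-0.83, SE 0.27) called in the authors' deposited table. The counts of these 4 lists were the same adjusted over the list alone. Of 6 tested male markers 0 were called, over all genes or adjusted over the list alone (median 0.46, test direction lower, cameraPR adjusted p = 0.979), and pkd-2 stood at -2.09 (SE 0.85, adjusted p = 0.065) in the authors' deposited table. Early embryo markers had 1 of 7 higher over all genes and 0 adjusted over the list alone (median 0.18, cameraPR adjusted p = 0.914), the called member being vet-6 (2.32, SE 0.82, adjusted p = 0.0351) in the authors' deposited table.

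Gene families defined by their name prefix were tested in the same way. Of 158 families tested, 33 passed, 13 toward higher and 20 toward lower values. The smallest p belonged to the pals family, many of whose members take part in the intracellular pathogen response, with 27 of 36 tested genes higher and 0 lower (median 3.90, cameraPR adjusted p = 6.82e-18). Its named members pals-28 and pals-11 rose by 8.24 (SE 0.69) and 7.80 (SE 0.74) in the authors' deposited table. Aspartyl protease genes (asp) fell, with 9 of 13 lower (median -1.28, cameraPR adjusted p = 9.58e-12), and asp-14 stood at -5.12 (SE 0.31) and asp-8 at -2.71 (SE 0.42) in the authors' deposited table. Carboxylesterase genes (cest) fell, with 21 of 32 lower and 2 higher (median -1.25, cameraPR adjusted p = 4.09e-08), and cest-31 (-3.21, SE 0.46) and cest-1.1 (-3.10, SE 0.75) led them in the authors' deposited table. The nspg family fell, with 8 of 12 lower (median -1.39, cameraPR adjusted p = 9.11e-08), and nspg-5 (-2.02, SE 0.57) and nspg-9 (-1.67, SE 0.18) led it in the authors' deposited table. Pumilio-type RNA-binding genes (puf) rose, with 6 of 10 higher (median 1.81, cameraPR adjusted p = 2.13e-07), puf-3 (2.97, SE 0.30) following puf-5 in the authors' deposited table. Mitochondrial ribosomal protein genes (mrpl) fell, with 24 of 38 lower (median -0.54, cameraPR adjusted p = 4.77e-06, and adjusted p = 0.064 at a preset correlation of 0.1), and mrpl-30 (-0.94, SE 0.19) and mrpl-12 (-0.93, SE 0.21) fell most in the authors' deposited table. Vacuolar proton pump genes (vha) fell, with 16 of 19 lower and 2 higher (median -0.66, cameraPR adjusted p = 5.12e-06, and adjusted p = 0.112 with the log2 fold change as the statistic), among them vha-6 (-1.17, SE 0.23) and vha-10 (-1.05, SE 0.19) in the authors' deposited table. The remaining families among the 10 with the smallest p were rpl, rps and his, the last with an adjusted p of 0.147 at a preset correlation of 0.1, and rps-26 (-0.90, SE 0.20) and rps-24 (-0.90, SE 0.19) led the rps genes in the authors' deposited table.

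Some groups held only a few called genes outside those fixed beforehand, and these were named after their values were seen. The single member of the major sperm protein list that fell was msp-71 (-0.91, SE 0.32), annotated as a pseudogene, the histone genes that rose were his-67 (1.02, SE 0.23) and his-68 (1.11, SE 0.20), and the remaining called vitellogenin was vit-3 (3.72, SE 0.72), in the authors' deposited table. For the microRNA machinery they were the microprocessor gene pash-1 (0.88, SE 0.25) and ebax-1 (-0.90, SE 0.35), and the remaining DAF-16-linked gene that rose was the superoxide dismutase gene sod-3 (1.42, SE 0.45), in the authors' deposited table. Innate immune genes that rose in the authors' deposited table included the lectin gene clec-60 (3.47, SE 0.38), fmo-2 (1.95, SE 0.54) and cnc-4 (1.67, SE 0.39). The ER chaperone gene hsp-4 rose (0.46, SE 0.14), and dnj-7 (-0.78, SE 0.20) and xbp-1 (-0.62, SE 0.18) fell, in the authors' deposited table. Among fatty acid genes acs-22 (-1.16, SE 0.17) and fat-3 (-0.41, SE 0.12) fell and the elongase gene elo-2 (0.85, SE 0.32) rose in the authors' deposited table. The remaining called genes of the epidermis and somatic gonad lists in the authors' deposited table were pah-1 of the epidermis (-0.37, SE 0.15), and inx-9 (0.65, SE 0.25) and ina-1 (-0.60, SE 0.24) of the somatic gonad list. The esterase genes that rose were cest-26 (0.93, SE 0.18) and cest-24 (1.29, SE 0.40), and the proton pump genes that rose were vha-7 (0.64, SE 0.16) and vha-18 (0.68, SE 0.20), in the authors' deposited table.

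Growth time and genotype could not be separated in any of these comparisons. The fold changes of the authors' deposited table appear drawn toward 0 for genes with few reads, so sizes for rare transcripts such as the microRNA genes are not comparable with those of abundant ones.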

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

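Settings with other preset correlations, ranks, fold changes as the statistic, a protein-coding background or without overlapping genes were chosen after seeing the data. Of the 5917 changed genes (3081 higher, 2836 lower), 3596 (2013 higher, 1583 lower) also had an absolute log2 fold change of at least 1. Under the other thresholds and filters the count ran from 4258 at an adjusted p under 0.01 to 6938 at an adjusted p under 0.1, within 1.5 times the main count in both directions. Of the 18 lists past the threshold, 16 kept their call at a mean of at least 50, 15 at a preset correlation of 0.05, 14 at 0.1, 16 with ranks and 12 with the log2 fold change as the statistic. No list changed direction in a called result. The log2 fold change as the statistic ended the calls of spermatogenesis (adjusted p = 0.0658), germline and meiosis (0.486), cell cycle (0.0756), DAF-16-linked (0.0841), fatty acid (0.0658) and body wall muscle (0.0841) genes. A mean of at least 50 ended those of germline and meiosis (0.0507) and fatty acid genes (0.0676), and without a filter ER and mitochondrial stress genes passed (0.0306). The 33 families past the threshold became 20 at a preset correlation of 0.05 and 10 at 0.1. A higher preset correlation makes this test allow more spread for a set, so a loss of calls follows from the setting itself. Calls lost in this way rest on the preset of 0.01. Without a filter on low values, the 6 mir-51 family genes gave a test direction of lower and an adjusted p of 0.117. Among named genes, nhl-2 (adjusted p = 0.057), drsh-1 (0.0711) and nhr-73 (0.0533) lost their call without a filter, while hsp-16.49 (0.0441) at a mean of at least 10, and lin-28 at a mean of at least 10 (0.0494) and of at least 50 (0.0455), gained one, since more or fewer genes entered the adjustment.

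No paired analysis was possible because the authors' deposited table has no values per sample. For the same reason the planned count models, normalizations, block, left-out samples, estimated correlation, fry test, pseudocounts, recovery of whole reads and splits of the samples were not run, so whether 1 sample drove a result is unknown. The depth per sample is unknown too, and the planned settings for microRNA sites were not run because no genome sequence was used.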

Other observations

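The tests described here of the pathogen response, germline size, oocyte number, X linkage and lin-41 were chosen only after the results were seen. The genes named here were also chosen only then. Other families past the threshold included chitinase-like genes (chil), with 12 of 22 tested genes higher and 3 lower (median 1.90, cameraPR adjusted p = 0.000777), math genes, with 21 of 40 higher and 3 lower (median 1.38, adjusted p = 5.08e-05), and skr genes of ubiquitin ligases, with 13 of 21 higher and 0 lower (median 2.12, adjusted p = 0.00625). The authors' deposited table gave chil-18 a log2 fold change of 8.85 (SE 0.62), chil-28, annotated as a pseudogene, 6.41 (SE 0.77) and chil-27, a gene induced by oomycetes, 6.33 (SE 0.79). By the authors' deposited table math-5 rose by 6.97 and math-34 by 6.45, and skr-11, annotated as a pseudogene, by 4.86 and skr-15 by 4.67. The pals regulator gene pals-22 stood at 0.49 (SE 0.40, adjusted p = 0.378) in the authors' deposited table. At a preset correlation of 0.05 the adjusted p was 0.0231 for chil, 0.0172 for math and 0.0679 for skr, and at 0.1 all of them lost their call, with 0.135 for both chil and math and 0.246 for skr. The skr family also lost its call at a mean of at least 10 and of at least 50.

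Of the let-7 microRNA family, not tested here as a list, these genes fell in the authors' deposited table, with log2 fold changes of -2.62 (SE 0.53, adjusted p = 9.45e-06) for let-7, -1.89 (SE 0.49, adjusted p = 0.000849) for mir-241 and -1.98 (SE 0.65, adjusted p = 0.0127) for mir-48. The family member mir-84 stood at -0.37 (SE 0.92, no adjusted p) in the authors' deposited table at a mean of 0.854. The noncoding gene WBGene00195705, on chromosome IV from 14033557 to 14034004 in the WBcel235 annotation and 4 bp from mir-52 on the same strand, rose by 3.33 (SE 0.90, adjusted p = 0.0014) in the authors' deposited table at a mean of 5.93. Loci annotated as small RNA genes 1094 and 1470 bp from mir-52 on the same strand, 21ur-2841 (2.43, SE 0.86, mean 3.17) and 21ur-39 (2.82, SE 0.86, mean 4.66), were also higher in the authors' deposited table. Their means are low, and total RNA reads of 150 bp do not show that the small RNAs themselves rose. Near the X-linked cluster ttr-34, 3805 bp from mir-56, rose by 2.23 (SE 0.48) in the authors' deposited table. Among tested protein-coding genes, the median log2 fold change was -0.17 for 2337 X-linked and 0.08 for 13821 autosomal genes, a difference of -0.25 (2-sided permutation test over genes, p = 1e-04, the smallest that 10000 permutations can give; genes are not independent). On the X chromosome 13.3% were higher and 22.6% lower, against 19.1% and 15.8% on the autosomes.

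All 12 intracellular pathogen response genes rose in the mutant. Reads shared between near-identical pals copies would leave the other members unmoved, yet 8 of 8 members outside that family were called higher. This count was already known from the rise of all 12. It argues against sharing between pals copies as the whole cause, and sharing among the other members was not tested. Closeness to the detection floor does not account for 9 of 12 members, called with a control mean of at least 10 as implied by the mean and the fold change plus 2 SE. It stays open for the remaining 3, F26F2.4, F26F2.3 and pals-5, which had the largest rises of the list. The implied means rest on fold changes that appear drawn toward 0, which would raise them. Members close to the bound of 10 are therefore less certain. So is F26F2.1, 1 of the 9, whose log2 fold change of 3.51 had an SE of 0.91. That SE lies near the largest of all genes, 0.923, so its implied control mean is unreliable. Longer growth or an exposure of the mutant cultures stays open beside the mutation itself: mutant and control shared 0 growth times, so these cannot be told apart. A candidate explanation is therefore either an infection or stress of the longer cultures or an effect of the genotype, and no sample tells which.

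Oocyte and yolk genes rose while molting genes fell. Of 10 adult-type cuticle genes 3 rose and 3 fell, so the list as a whole did not decide between the readings below (cameraPR adjusted p = 0.979). A germline enlarged evenly in the mutant pool would raise oocyte genes and germline and meiosis genes alike. The oocyte median, however, lay 2.14 above theirs on the log2 scale (2-sided permutation test over genes, p = 2e-05, the smallest that 100000 permutations can give). Genes are not independent, and this p does not measure the spread between samples. The gap, already visible in the list medians, argues against an evenly enlarged germline as the whole cause, though not as a part of it. It does not bear on a germline enlarged mainly in oocytes. More oocytes alone would not raise the vitellogenins, made in the intestine, of which 4 of 5 rose. That vitellogenin count was already known when the test was chosen. A mutant pool further along towards adulthood stays open. Of the adult-type cuticle list, col-19 (7.26), col-62 (3.93) and col-7 (2.91) rose in the authors' deposited table. The list members bli-1 (-2.89), bli-2 (-2.71) and col-38 (-1.81) fell in the authors' deposited table. Without a time course this split speaks neither for nor against that reading. A list of 10 late reproductive genes was added for this, and 10 of 10 were called higher (median 2.88), but most are eggshell and oocyte genes, and the list, with ule-2, ule-3 and ule-4, was picked after ule-5, ule-1 and a summary of the cpg family were seen, so it decides neither way. Genotype and growth time remain untested as sources of such a shift.

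The rise of lin-41 went with falls of let-7, mir-241 and mir-48. Loss of repression by the let-7 family could raise lin-41, but of lin-14, lin-28, hbl-1 and daf-12, 0 were called higher and 1 lower, which decides neither way. With only genes at a mean of at least 10 or of at least 50, lin-28 was called higher. More oocytes in the mutant pool could also raise lin-41, which oocytes express: its log2 fold change of 2.09 lay within the range of the oocyte genes, 1.18 to 5.23. Both stay open as hypotheses, and mature microRNAs were not analysed here.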
